A study of Caenorhabditis elegans with 4 samples.

How the data were processed

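The series is a chromatin immunoprecipitation and sequencing (ChIP-seq) experiment in Caenorhabditis elegans. It holds 4 samples, which are 2 anti-GFP ChIP samples and 2 samples of input DNA, each numbered 1 and 2 in its title. Groups and replicate numbers were taken from those titles. Per the labels' protocols, worms were grown at 20 °C, crosslinked with 2% formaldehyde and sonicated, and 10% of the cleared lysate was kept as input before immunoprecipitation with affinity-purified anti-GFP antibodies. The labels do not say whether the replicates came from separate cultures. Any agreement between the lists therefore measures the spread between these samples, which may be technical.

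The deposited data are 3 peak lists, one for each ChIP sample and one combined list of the series. Per the file headers, all 3 lists use the WormBase WS180 genome build, and the caller named for each of the 4223 peaks is PeakSeq. PeakSeq compares ChIP reads in a region with reads of a control. The aligner, the PeakSeq version, its settings, the filters and the way in which the replicates were combined are not given in the sources used here. Each peak has a start, an end and a value that the authors deposited as a q-value. No file of an input sample was used here. Positions are 1-based WS180 coordinates.

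The deposited q-values were examined before they were used to rank peaks. Each of the 4223 values equalled, within a relative tolerance of 1e-09, the lower binomial tail (probability 0.5) of a pair of whole numbers. For 4220 values a pair was found among totals below 1500, and for the other 3 among totals up to 40000, the only values searched that far. No value matched a further pair in the range where its own was found. After each value was raised by 1 part in 100000, 0 of 4223 matched a pair among totals below 1500. Of the 449 distinct values in the replicate 1 list, 213 also occurred in the replicate 2 list. A value corrected by rank and list length would not take such a form. The deposited numbers were therefore treated as uncorrected p-values of a comparison between both numbers of the pair. The larger number is called the ChIP tags of a peak and the smaller one the control tags. This naming follows the published PeakSeq method, in which ChIP tags are compared with control tags scaled to the ChIP library, and no file names these quantities. Enrichment means ChIP tags divided by control tags. Its 95% interval is the exact Clopper-Pearson interval of the ChIP share turned into a ratio. It covers counting error only and treats the scaled control tags as counted. Total reads per library are unknown, so the depth of each library is unknown. The number of regions tested was unknown too, so no corrected value was computed.

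Peaks were counted as shared where they overlapped by at least 1 bp. The overlap of the replicate lists was compared with 1000 placements of the replicate 2 peaks at random on their own chromosome, in a one-sided test. The smallest p that these can give is 0.001. Agreement of strength was measured as the correlation of −log10 of the deposited values across shared peaks, with 100000 permutations in a two-sided test, for which the smallest p is 1e-05. For the part that a shared control level gives, replicate 2 enrichment was shuffled 1000 times over the shared peaks, the control tags of each peak were kept, and the tails were computed again (one-sided). The shuffle also removes any agreement in enrichment that shared control tags give, so that part was not measured. Where a peak had several partners, the strongest was used. The share of peaks on each of 6 chromosomes was compared with its share of the length by an exact binomial test of both sides, with Benjamini-Hochberg adjustment over the chromosomes. The length of a chromosome was taken as the end of the last peak listed on it in any list, because no WS180 sequence was used here. For tag comparisons between replicates, pairs of peaks with a single partner each and edges that differed by at most 80 bp in all were used, with intervals from 1000 bootstrap draws over peaks. Peaks are not independent replicates.

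The peaks named are the 10 combined-list peaks with the smallest deposited values that also overlap a peak in both replicates. This rule, the tests and most alternatives were fixed before the data were examined. The other alternatives, and all comparisons of tag pairs, were chosen after seeing the data. Alternatives were an overlap of 50% of both peaks, centres within 200 bp, the better-scoring 50% of each list, each replicate list in place of the combined one, a circular shift in place of random placement, lists without chromosome IV (for the chromosome shares also each replicate list and the peaks held by both), and chromosome length counted from the first listed peak. For closely matched peaks they were a limit of 40 bp, all single partners, the better-scoring 50% and lists without chromosome IV or without the strongest peak. Tags of both replicates were compared only over shared regions, and the deposited values were used to rank peaks within each list and to correlate shared peaks. Planned tests of gene position, of the E-box sequence and of gene groups were not run. They need a WS180 genome or annotation, and the gene table at hand is of the WBcel235 assembly. No peak was assigned to a gene for the same reason. The gene table was used only for the chromosome on which hlh-30 and unc-119 lie.

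The code was tested on simulated data. For the overlap of the replicate lists, 390 shared peaks were found among 649 where 389 had been planted. For the tag pairs, 1000 of 1000 simulated pairs were recovered. For the chromosome shares, lists with a chromosome IV share lowered to 50% were called in 100 of 100 simulations, and any chromosome was called in 5 of 100 unchanged ones. Simulated peaks were drawn independently of each other, so the rate of false calls for peaks that occur in groups was not measured. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used.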

Results

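Binding of HLH-30 to the genome was measured in late embryos of the nematode C. elegans. HLH-30 is a basic helix-loop-helix transcription factor, the worm counterpart of mammalian TFEB, a regulator of autophagy and lysosome genes. The strain, OP433, carries a transgene that expresses HLH-30 fused to EGFP and FLAG, together with unc-119(+) to rescue the unc-119(ed3) background. The gene hlh-30 lies on chromosome IV and unc-119 on chromosome III. Antibodies to GFP were used for the immunoprecipitation, and input DNA served as control. The question addressed is where in the genome the fusion protein was bound at this stage. ChIP replicate 1 gave 649 peaks, ChIP replicate 2 gave 1338, and the combined list held 2236.

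The peaks were short. Median width was 343 bp in replicate 1 (quartiles 284 and 456), 381 bp in replicate 2 (312 and 509.75) and 352 bp in the combined list (281 and 476.25). The combined peaks covered 0.936 Mb. The read depth of the samples is unknown, and the tag numbers given are those whose binomial tail equals a peak's deposited value, read as ChIP tags and scaled control tags. A median combined peak held 69 ChIP tags (quartiles 50 and 105) against 19 control tags (13 and 28), an enrichment of 3.68-fold (2.97 and 4.74). Median enrichment was 4.57-fold in replicate 1 and 4.86-fold in replicate 2. Deposited values were at most 0.000156 in replicate 1, 0.000111 in replicate 2 and 0.000168 in the combined list.

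Nearly all sites called in replicate 1 were called again in replicate 2, which held many further sites. Of the 649 replicate 1 peaks, 608 overlapped a replicate 2 peak, or 93.7% (95% Clopper-Pearson interval 91.5 to 95.4). Of the 1338 replicate 2 peaks, 602 overlapped a replicate 1 peak, or 45.0% (42.3 to 47.7). Random placement of the replicate 2 peaks gave a mean of 8.34 overlapping replicate 1 peaks and a maximum of 18 (permutation p = 0.001, the smallest that 1000 placements can give). This comparison does not allow for control reads that both replicates may share, so the part of the overlap that these give is unknown. All of the 100 strongest peaks of each replicate were present in the other. The 41 peaks found in replicate 1 but not in replicate 2 were weak, with a median −log10 value of 4.48 and a maximum of 6.33. The 736 peaks of replicate 2 without a partner had a median of 5.21 and a maximum of 19.8.

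Sites that were strong in one replicate were strong in the other. Across the 608 shared peaks, −log10 of the deposited values correlated with Pearson's r of 0.93 and Spearman's rho of 0.77 (permutation p = 1e-05 for each, the smallest possible, and adjusted p = 1e-05 over both). This is a correlation across peaks, which are not independent replicates. Without the 2 peaks farthest from the median of replicate 1, r was 0.90 and rho 0.77. The control tags of both replicates were nearly equal, and shared control tags alone correlate the values. With replicate 2 enrichment shuffled over the peaks and each peak's control tags kept, rho averaged 0.14 (maximum 0.24) and r averaged 0.66 (maximum 0.70), both below the observed values (permutation p = 0.001, the smallest possible). Without the strongest listed peak, r was 0.90 and averaged 0.11 after shuffling. Shuffling also removes any agreement in enrichment that shared control tags give. The agreement is therefore not shown to exceed all that a shared control would give. Replicate 2 had the higher enrichment at 258 of 281 closely matched peaks. Median enrichment at these peaks, a comparison chosen after seeing the data, was 5.0-fold in replicate 1 and 6.73-fold in replicate 2, and the median ratio of replicate 2 to replicate 1 was 1.39 (95% bootstrap interval 1.33 to 1.42).

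**Figure D1:**
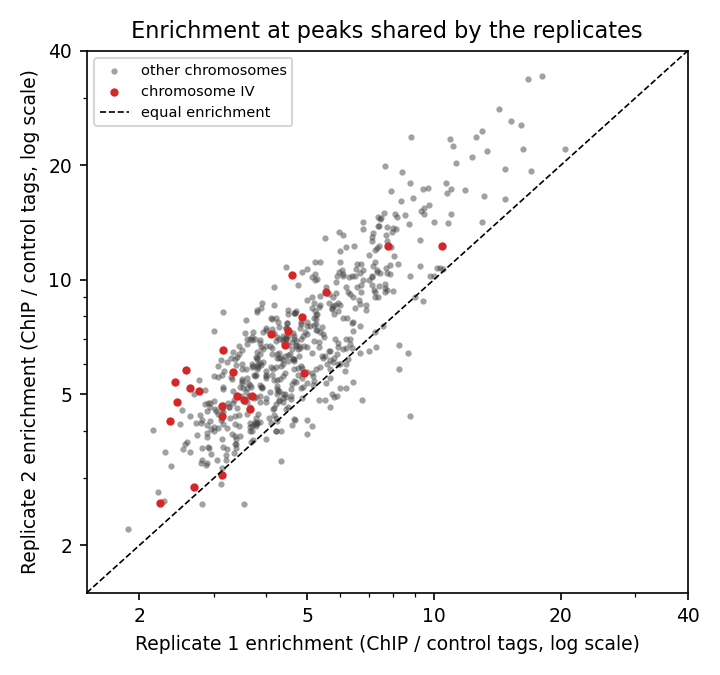
Enrichment (ChIP tags divided by control tags, log axes) in replicate 1 and replicate 2 at the 596 shared peaks with a single partner in each list. Each point is a peak, red points lie on chromosome IV, and the dashed line marks equal enrichment. In 553 of the 596 peaks replicate 2 is above the line.

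Peaks with the smallest deposited values were found on every chromosome, though on chromosome I only through a wide peak enriched 1.91-fold. Of the 10 combined peaks with the smallest deposited values that both replicates held, 3 lay on chromosome III, 2 each on IV and X, and 1 each on I, II and V. All 10 were among the 26 strongest peaks of replicate 2 and the 23 strongest of replicate 1. Enrichment was higher in replicate 2 than in replicate 1 at 10 of 10. In WS180 coordinates, the highest enrichment of these was at chromosome III 10758923 to 10759478. This 556 bp peak held 549 ChIP tags against 23 control tags, or 23.9-fold (95% counting interval 15.7 to 38.0). Its enrichment was 18.1-fold (10.1 to 35.5) in replicate 1 and 34.3-fold (18.9 to 69.2) in replicate 2. A 696 bp peak at chromosome X 7951396 to 7952091 reached 15.6-fold (11.3 to 22.2), with 609 ChIP tags against 39. Chromosome III 3801198 to 3801933 reached 13.1-fold (9.47 to 18.5). Chromosome X 16929363 to 16930509 reached 11.6-fold (8.88 to 15.3), and its value was the second smallest of the list (−log10 of 137).

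The other strong sites were less enriched in the combined list, though not in each replicate. On chromosome IV, the peak at 2601909 to 2602839 was enriched 11-fold (8.34 to 14.8) and the one at 10935191 to 10936451 was enriched 6.43-fold (5.29 to 7.88). The second of these overlapped 2 separate peaks in each replicate list. A 1714 bp peak at chromosome II 6347256 to 6348969 was enriched 7.87-fold (6.22 to 10.1) and also overlapped 2 peaks in each replicate, the stronger of which was enriched 8.84-fold (5.49 to 15.1) in replicate 1 and 23.7-fold (13.04 to 48.1) in replicate 2. Chromosome III 349446 to 350521 reached 9.31-fold (7.10 to 12.4), and chromosome V 9343108 to 9344687 reached 8.25-fold (6.57 to 10.5). The latter was 9.41-fold (6.31 to 14.6) in replicate 1 and 17.4-fold (11.6 to 27.1) in replicate 2. Its combined peak held 693 ChIP tags against 84 control tags, replicate 1 held 254 against 27, and replicate 2 held 434 against 25. The combined control tags thus exceeded those of both replicates together. The 3 enrichments may therefore not cover the same stretch.

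The smallest deposited value did not mark the most enriched site. It belonged to the widest peak, 3649 bp at chromosome I 15063999 to 15067647, which is also the last peak listed on that chromosome. There, 8329 ChIP tags stood against 4355 control tags, an enrichment of 1.91-fold (1.84 to 1.98) with a −log10 value of 277. Only 9 of the 2236 combined peaks had a lower enrichment. The ratio was 1.88-fold (1.80 to 1.97) in replicate 1 and 2.205-fold (2.105 to 2.31) in replicate 2. The control level of this peak was far above the median of combined peaks on chromosome I, 58.2 control tags per kb. Whether this peak marks a bound site was not tested.

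The combined list contained nearly every replicate peak and 911 peaks that neither replicate held. It lacked 2 of the 649 replicate 1 peaks and 44 of the 1338 replicate 2 peaks. Of the 2236 combined peaks, 600 were held by both replicates, or 26.8% (25.01 to 28.7), 686 by replicate 2 alone, 39 by replicate 1 alone and 911 by neither, or 40.7% (38.7 to 42.8). Peaks held by both had a median enrichment of 5.5-fold (quartiles 4.28 and 7.12) with a median of 138 ChIP tags. Peaks held by neither had 3.21-fold (2.75 and 3.90) with 50 ChIP tags. Peaks of replicate 2 alone had 3.46-fold (2.85 and 4.17), and those of replicate 1 alone had 4.05-fold (3.39 and 5.0). All of the 200 strongest combined peaks were held by both replicates. At the 587 combined peaks with a single partner in each replicate, the combined ChIP tags were a median of 1.01 times the sum of both replicates (quartiles 0.948 and 1.09). The combined list is therefore not shown to be separate evidence. If it was made from the reads of both replicates, its strong peaks would tend to be held by both for that reason.

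Peaks were not spread over the chromosomes in proportion to length. Chromosome IV held 143 of the 2236 combined peaks, or 6.40% (5.42 to 7.49), where its length gave 17.3% (exact binomial test, adjusted p = 3.79e-52). This is 0.369 times the expected share, or 8.25 peaks per Mb. Chromosome III held 478 peaks, 1.55 times its expected share (34.7 per Mb, exact binomial adjusted p = 4.00e-22), and chromosome II held 424, 1.24 times (27.8 per Mb, adjusted p = 4.98e-06). Chromosome V held 385, 0.826 times its expected share (18.5 per Mb, exact binomial adjusted p = 2.58e-05). The X chromosome held 461, 1.17 times (26.1 per Mb, exact binomial adjusted p = 0.000372). Chromosome I, with 345 peaks (22.9 per Mb), did not pass the test (1.02 times, exact binomial adjusted p = 0.636). These tests treat peaks as independent, and peaks lay closer together than random placement gives.

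The shortage on chromosome IV was present in each replicate, with 29 of 649 peaks in replicate 1 (4.47%) and 92 of 1338 in replicate 2 (6.88%). Both replicates may have been tested against the same control reads, so their lists are not shown to be separate evidence. The surplus on chromosome III was likewise present in each, at 23.9% and 22.1% of peaks against an expected 13.8%. The surplus on X passed the test in each replicate (1.37 and 1.31 times) and among peaks held by both (1.41 times). The call for II depended on the list. Chromosome II did not pass the test in replicate 1 (1.09 times, exact binomial adjusted p = 0.392) or among peaks held by both replicates (1.11 times, adjusted p = 0.281). With chromosome IV left out, the X chromosome was near its expected share in the combined list (22.03% against 21.4%, exact binomial adjusted p = 0.455). It stayed above that share in replicate 1 (25.3%, exact binomial adjusted p = 0.0275) and replicate 2 (24.8%, adjusted p = 0.00459). Chromosome I was then below its share in the combined list (0.903 times, exact binomial adjusted p = 0.0465).

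**Figure D2:**
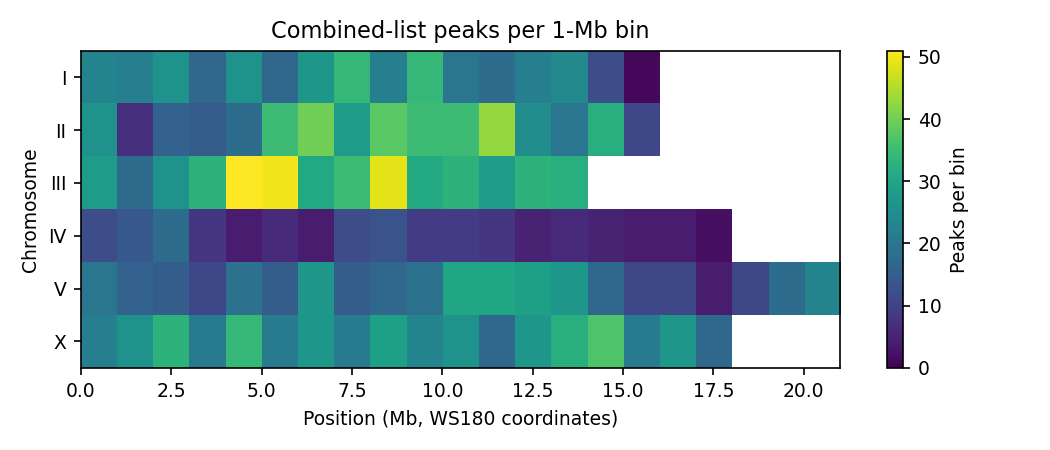
Number of combined-list peaks in each 1-Mb bin (colour) along each chromosome, with position in Mb (WS180) on the horizontal axis. Chromosome III reaches 51 peaks in a bin, while no bin of chromosome IV holds more than 18, and the last bin of a chromosome is only partly covered.

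**Figure D3:**
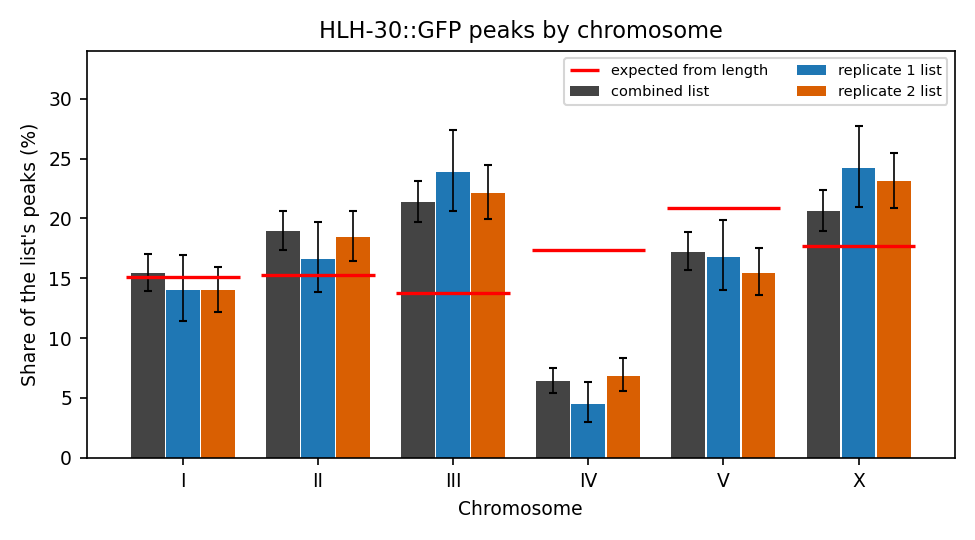
Share of each list's peaks on each chromosome (bars, in percent, with 95% exact binomial intervals) for the combined, replicate 1 and replicate 2 lists. Red lines give the share expected from chromosome length, and chromosome IV lies far below its 17.3% in all 3 lists, while chromosome III lies above its 13.8%.

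Peaks on chromosome IV, few in number, had a higher control level than peaks elsewhere. Median control tags per kb of peak were 77.6 on chromosome IV and 51.1 on the others in the combined list, a ratio of 1.52 (permutation of peak labels, p = 1e-05, the smallest possible). The ratio was 1.74 in replicate 1 and 1.89 in replicate 2, each with a permutation p = 1e-05. ChIP tags per kb of peak were also highest on chromosome IV in each list. In the combined list their median was 232 there and between 177 (V) and 199 (I) elsewhere. Median enrichment of combined peaks was 3.00-fold on chromosome IV and between 3.50-fold (I and X) and 4.0-fold (III) elsewhere. These values cover listed peaks only. With more control tags, a peak needs more ChIP tags to reach the same deposited value, and it can reach that value at a lower enrichment. The ChIP level and enrichment on IV are therefore not shown to be traits apart from its control level.

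**Figure D4:**
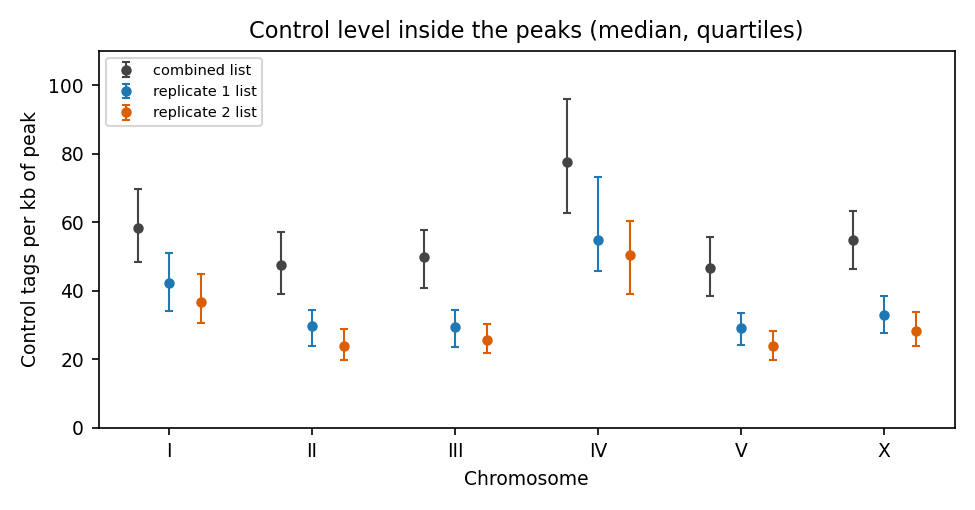
Control tags per kb of peak on each chromosome (points are medians over peaks, bars run from the lower to the upper quartile) in the 3 lists. Chromosome IV has the highest median in every list, 77.6 in the combined one.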

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

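The alternatives without chromosome IV, the length from the first listed peak, and all tests of control tags and closely matched peaks were chosen after the results were seen. The overlap of the replicate lists, the rank agreement, the shortage on chromosome IV, the surplus on III and the deficit on V kept their direction and their side of 0.05 under each alternative run for them. Chromosome V was, however, above its share among the 559 weakest combined peaks, a set chosen after seeing the data and not tested against length. Of 63 alternative values with a p, 50 kept both direction and side of 0.05, and of 33 without one, 32 were not moved. The overlap of replicate 1 with replicate 2 ran from 88.0% with 50% of both peaks to 96.3% for the better-scoring 50% of each list, and rho from 0.76 to 0.80. The share of combined peaks held by replicate 1 moved from 28.6% to 26.0% when 50% of both peaks had to overlap. On the log2 scale, chromosome I, at 0.03 and short of the threshold, turned to -0.11 and -0.10 in the replicate 2 and 1 lists and -0.040 among peaks held by both, all short of it too. The surplus on chromosome II fell from 0.31 to 0.12 in the replicate 1 list and 0.15 among peaks held by both, no longer past the threshold; these sets have fewer peaks, and no other cause was tested. Leaving out chromosome IV lowers the other shares against expectation by its construction. In the combined list without it, X went from 0.22 to 0.044, no longer past the threshold, chromosome I to -0.15, past it, and chromosome II to 0.13, still past it (exact binomial adjusted p = 0.0465, in a range of 7.91e-06 to 0.707 over its alternatives). In the replicate 1 list, the replicate 2 list and the peaks held by both, each without chromosome IV, X kept its surplus past the threshold. There chromosome I was at -0.31, -0.28 and -0.25, the last short of the threshold, and chromosome II at -0.085, 0.10 and -0.057, none past it. With each replicate left out in turn, chromosome II ran from 0.12 to 0.27 and chromosome IV from -1.96 to -1.34. The enrichment ratio of the replicates ran from 1.34 to 1.46, and the control ratio on chromosome IV from 1.495 to 1.89. No paired analysis was possible because the results come from peak lists and no file of the input samples, which share the replicate numbers, was used here. The planned results on gene position, the E-box and gene groups, with their alternatives, were not run, for lack of a WS180 genome and annotation. Library depth is unknown, so a site missing from a list is not shown to be unbound.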

Other observations

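All tests in this part were chosen after the results were seen. On chromosomes II, III and V, peaks were more frequent in the centre than in the outer parts. With each chromosome divided into 3 equal parts, the middle part held 42.9% of the peaks of chromosome V (95% interval 37.9 to 48.0, exact binomial test against 33.3%, adjusted p = 0.000706). It held 41.5% on chromosome II (exact binomial adjusted p = 0.00135) and 38.7% on chromosome III (adjusted p = 0.0304). Chromosome I gave 38.8% (33.7 to 44.2, exact binomial adjusted p = 0.0516) and chromosome IV gave 35.7% (27.8 to 44.1, adjusted p = 0.595), neither of which passed. On the X chromosome the middle part held 30.8% (26.6 to 35.2, exact binomial adjusted p = 0.307). These tests treat peaks as independent, although peaks occurred in groups, so the call on III, with a share close to that of I, is uncertain. As background, genes are denser in the centres of C. elegans autosomes than in their arms, and the X chromosome shows less of such a division. The densest 1-Mb bins lay on chromosome III, with up to 51 peaks.

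Peaks also occurred in groups. Another combined peak had its centre within 2000 bp of 426 of the 2236 peaks, or 19.1%, against a mean of 215 and a maximum of 285 in 1000 random placements (permutation p = 0.001, the smallest possible). The median distance to the nearest peak was 8713 bp, against a mean of 14090 bp in random placements. This spacing was not compared with that of genes. Chromosome IV held 12 of the 100 strongest combined peaks and 131 of the other 2136, or 6.13% (Fisher's exact test, two-sided, p = 0.0326). That limit of 100 was chosen after seeing the list, and the 559 strongest peaks included 34 on chromosome IV, or 6.08%, against 109 of the other 1677 (Fisher's exact test, adjusted p = 0.919).

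The weakest combined peaks had another distribution over the chromosomes. Chromosome V held 135 of the 559 weakest peaks, or 24.2%, above the 20.9% its length gives, and 14.9% of the rest (Fisher's exact test, adjusted p = 6.68e-06). The X chromosome held 85 of these 559, or 15.2%, below the 17.7% its length gives, and 22.4% of the rest (Fisher's exact test, adjusted p = 0.000674). The other 4 chromosomes did not pass this test. These tests compare the weakest peaks with the rest, and the shares of the weakest peaks were not tested against length. No explanation was tested.

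A higher control level in the peak calls is a candidate explanation for the shortage of peaks on chromosome IV, where control tags per kb were 1.52 times those of the other chromosomes. The other chromosomes followed it only in part. V had the lowest control level (46.6 per kb) and 0.826 times its expected share of peaks. I (58.2) and X (54.9) had 1.02 and 1.17 times theirs, but the shortage on IV raises these shares. With IV left out of the combined list, I was at 0.903 times and X at 1.03. II (1.096) and III (1.37), with lower control levels, were above both, but V was at 0.729. In the replicate 1 and 2 lists without IV, I (0.804 and 0.823) was again below II and III. There X (1.185 and 1.16) was, however, above II (0.943 and 1.07). Extra DNA of 1 segment, such as a transgene's copy of the hlh-30 region, would raise only that part if control tags were scaled alike on all chromosomes. Control tags were above the median of the other chromosomes in 9 of 9 segments of 2 Mb. That condition is in doubt. At closely matched peaks the control ratio of replicate 1 to replicate 2 differed by chromosome, from 1.02 on I to 1.13 on IV. The segments argue against extra DNA of 1 segment only if the condition holds, and otherwise cannot decide. Fewer bound sites on chromosome IV may account for a remainder. When the control tags of all other combined peaks were raised 1.52 times, 1088 of 2093 stayed within the list's largest deposited value. The density of peaks on chromosome IV relative to the others then went from 0.326 to 0.626 (0.528 to 0.738). Each replicate list was raised by its own ratio. This gave 0.490 (0.328 to 0.704) in replicate 1, raised 1.74 times, and 0.769 (0.620 to 0.943) in replicate 2, raised 1.89 times. That remainder stays open. Chromosome V then held as few peaks per Mb in the combined list (8.25 on each) and fewer in replicate 2 (4.65 against 5.31). In replicate 1 chromosome IV was lowest (1.67 against 2.32 on I), but with an upper limit of 2.40. These comparisons of single chromosomes are rough, because 1 factor per list was applied to chromosomes of unequal control level. In replicate 1 that level was 42.1 per kb on I and 29.1 on V. The control level was also measured only inside listed peaks.

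The control tags of both replicates were nearly equal, although the series lists 2 input samples: without the strongest listed peak, they differed by at most 1 tag at 243 of 280 closely matched peaks. The squared difference of control tags divided by their sum, about 1 for independent unscaled reads of equal depth, averaged 0.0516 over these, 0.0667 (0.0458 to 0.106) with the strongest peak, and 0.246 (0.185 to 0.319) over all 596 single partners, whose edges differ more, against 2.05 for ChIP tags at the closely matched peaks. A candidate explanation is that both replicates were tested against the same control reads, for instance pooled inputs. Separate controls that were scaled down remain possible if each held many reads per scaled tag, 14.997 by the average of 0.0667 and fewer by that of 0.246, which the lists cannot exclude. No biological explanation was tested.

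Replicate 2 gave more peaks than replicate 1, and the tag pairs bear on whether depth or enrichment differed. Control tags in replicate 1 were 1.06 times those in replicate 2 at closely matched peaks (1.05 to 1.07). On the reading that control tags were scaled to each ChIP library by 1 factor, this would argue against a deeper library in replicate 2. That reading is uncertain, because the ratio differed by chromosome, from 1.02 (1.004 to 1.04) on I to 1.13 (1.09 to 1.16) on IV. A single factor applied to the same control reads would not give such a difference. The ratio was nevertheless above 1 on each chromosome. Over all single-partner peaks, whose edges differ more, the control ratio of replicate 1 to replicate 2 was 1.0 (0.969 to 1.02). Enrichment was 1.39 times higher in replicate 2, which is consistent with a more efficient immunoprecipitation there, though a biological difference between the samples was not tested.

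By chromosome, the control ratio of replicate 1 to replicate 2 ran from 1.02 (1.004 to 1.04) on chromosome I to 1.13 (1.09 to 1.16) on chromosome IV, the latter over 14 peaks. At the strongest listed peak, near the end of chromosome I, the combined list held 8329 ChIP tags where both replicates summed to 10999, a ratio of 0.757, unlike the median of 1.01 at other peaks. The narrowest combined peaks were 2 bp (chromosome II 3311022 to 3311023) and 3 bp (chromosome V 7863986 to 7863988), each with 16 ChIP tags against 1 control tag.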
